A study of Mus musculus with 4 samples.

How the data were processed

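Liver of C57/BL6J mice was profiled for H3K27 acetylation (H3K27ac) by CUT&Tag in 4 libraries, 2 from sham-operated mice and 2 taken 12 h after 70% partial hepatectomy (PHx). Per the labels' protocols, nuclei came from flash-frozen liver and were bound to concanavalin A beads. An anti-H3K27ac antibody and a pA-Tn5 transposase were added in turn, and the amplified libraries were sequenced as 150 bp paired-end reads. The labels name 2 replicates per group without saying which animals they came from, so their spread may be technical. The labels give no time for the sham libraries and the series' design text speaks of 0 h, so time after surgery and time of day may differ between the groups along with hepatectomy.

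The authors deposited 1 annotated table of regions per group. The submitters' processing notes name Bowtie2, SEACR, ChIPseeker and DiffBind, with no versions and no roles, and the builds GRCm39 and mm39, which are names of the same mouse assembly. Caller thresholds and filters are not given in the sources used here. Per the file headers, the deposited values are the start, end and width of each region in bp, its annotation class, the assigned gene with its coordinates and strand, and the distance to that gene's transcription start site (TSS). Each row also lists the peaks of library 1 and library 2 that were joined into the region, and every region held at least 1 peak of each library. The tables hold no signal, score or read count, so the depth of the libraries is unknown and only presence, position and width of regions could be compared. Merging within a group means that a peak called in 1 library alone is not listed, and that a region spans the union of its peaks. A group whose peaks were called broader therefore has wider regions and can cover more TSSs without any other change.

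From these tables the number, covered length and width of regions were computed, with shares given exact Clopper-Pearson 95% intervals. These intervals cover counting error only, since regions are not replicates. Regions were called overlapping when they shared at least 1 bp, with bedtools 2.31.1, and chance overlap came from 100 shuffles of the regions within their chromosomes with widths kept. Those shuffles ran over the whole chromosome, including stretches where reads may not map, so they give a low estimate of chance. Regions of which each overlapped exactly 1 region of the other group, and the reverse, were compared in width as pairs.

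A gene was called marked in a group when a region overlapped its TSS ± 1 kb. No genome or annotation of the files' build was used, so the TSS was the most upstream start listed for the gene in either table. A total of 10925 gene names had such a TSS, and 7090 were protein-coding by a mouse RefSeq gene table of another build (GRCm38.p6), used only for names, biotypes, gene order and the share of genes on the X chromosome; 264 names found no match there. A wide region names only 1 gene, so a gene without a listed TSS can still lie inside a region, and such genes were left out of counts. "PHx only" and "sham only" describe genes or regions found in the merged list of that group and not in that of the other.

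Before the data were examined, 22 gene lists with 306 genes were fixed. For each list the net count, PHx only minus sham only, was placed among 10000 random lists of protein-coding genes of the same size, matched on the decile of the larger of the gene's width ranks in the groups. A list was called apart when at most 2.5% of random lists were as high, or as low. This percentile describes these lists and is no p-value. A further 4 lists (endothelial, Kupffer cell and macrophage, stellate cell and fibroblast, hepatocyte) were added after the first result was seen and before their members were looked up. The comparison of region width per list was also added after the tables were seen.

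The genes named in the text follow a rule fixed beforehand. It takes, in each list, up to 4 members marked in one group only and up to 2 marked in both, the 10 protein-coding genes of each group only, the 5 distal regions of each group only and the 5 widest regions. The rule ranked them by the authors' signal and, where no signal is given, by width, so width took its place; all members of a list could be named where the list is described, and values of some members are not reported here. Thresholds planned on signal were likewise replaced by width, an alternative added after the tables were seen. Ranking by width favours genes with a wide PHx region, so the widths named below need not be typical of their lists. Motif shares for 20 motifs, which need the genome sequence, and tests per gene between libraries, which need values per library, were not analysed here.

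Peak numbers in the tables run in genomic order within each library. Numbers missing between neighbouring regions were therefore counted as peaks of that library outside any listed region, called unused numbers below; a number is also unused where its region is not among the rows analysed here. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data made from these tables. Dropped and added regions and planted peak numbers were recovered in 100.0% of cases. The simulated regions were not widened or joined, and added regions lay in long gaps. This recovery therefore checks the code and not the calls under unequal widths. Of 200 random lists, 0.5% passed the upper limit and 1.5% the lower. Of 50 lists of 12 genes with 6 planted PHx-only members, 88.0% passed. Alternatives were stricter sets of regions by width, other definitions of overlap, other TSS windows and gene assignments, unmatched random lists, and settings that used the unused numbers.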

Results

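H3K27ac, a histone mark of active promoters and enhancers, was mapped in mouse liver from sham-operated animals and from animals 12 h after removal of 70% of the liver, with 2 libraries per group. In CUT&Tag an antibody directs a transposase to the mark, and the enzyme cuts and tags the DNA there. Partial hepatectomy is a standard model of liver regeneration, and the comparison asks how acetylated regions differ between the resting and the regenerating organ. Each group had 1 merged list of regions on GRCm39, without signal values. The depth is unknown, no value has a replicate error, and no p-value is given.

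The PHx 12 h list held fewer but wider regions than the sham list. It had 10170 regions covering 197 Mb, against 11602 regions covering 122 Mb in sham, a ratio of covered length of 1.62. The median width was 14551 bp (quartiles 10184 and 23019 bp) after PHx and 8153 bp (quartiles 5928 and 12299 bp) in sham, a ratio of 1.78. Widening was seen at the promoter of the albumin gene Alb, where the region measured 10096 bp in sham and 18025 bp after PHx. At the promoter of Actb, which encodes cytoplasmic actin, it measured 19265 and 40391 bp. Of the 6164 regions that matched 1 to 1 between the groups, 89.0% were wider after PHx, with a median ratio of 1.49 (quartiles 1.15 and 2.08). The median ratio was 1.97 in the 1541 pairs narrowest in sham and 1.17 in the 1541 widest. Predicted genes aside, the largest ratio of a pair was 17.7 at an intron of Zfp618, and the smallest was 0.410 at Nqo2, both singled out after their values were seen. A single PHx region overlapped several sham regions in 1614 cases, and the reverse occurred in 85. The libraries of the PHx group were not alike: library 2 alone was split into several peaks in 1173 regions and library 1 alone in 246, against 551 and 776 in sham.

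**Figure D1:**
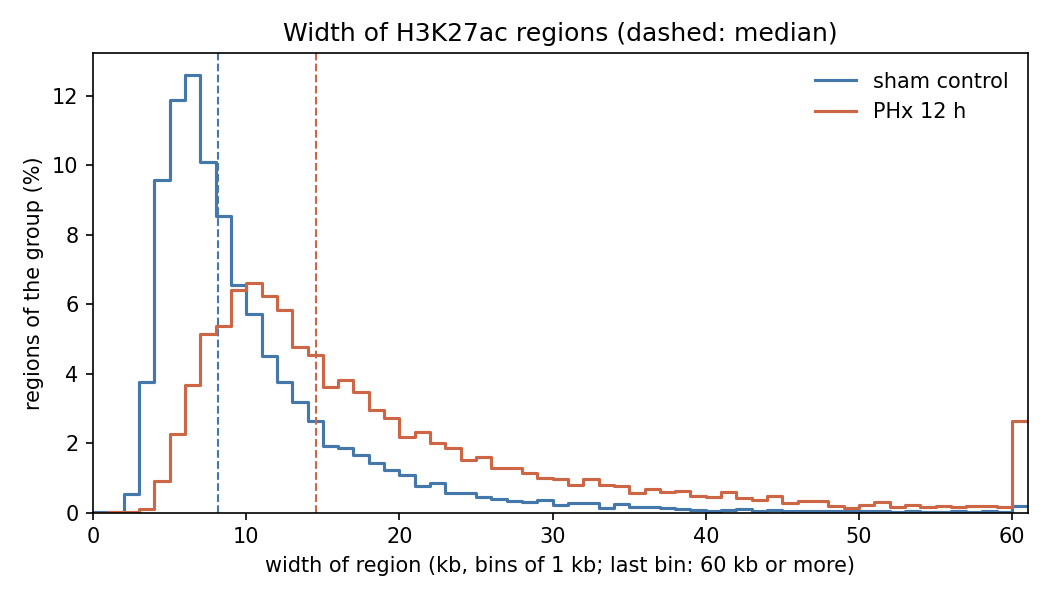
Distribution of region width, in bins of 1 kb (x axis, kb), as percent of the regions of each group (y axis), for sham control (blue) and PHx 12 h (orange), with dashed lines at the medians of 8153 and 14551 bp. The last bin collects regions of 60 kb or more, 0.190% of sham and 2.64% of PHx regions.

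Promoters made up a larger share of the PHx list. By the authors' annotation 75.4% of PHx regions (95% interval 74.5 to 76.2%) and 67.8% of sham regions (66.9 to 68.6%) were promoter regions. Intron regions were the smaller share after PHx, with 5.92% (5.47 to 6.40%) against 10.4% (9.85 to 10.96%) in sham. Distal intergenic regions were 6.48% (6.01 to 6.98%) and 7.21% (6.74 to 7.69%) of the lists. A TSS lay inside 72.3% of PHx and 63.2% of sham regions. Wider regions reach a TSS more often, which by itself raises this count and the promoter share.

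Counting any shared base, most regions overlapped between the groups. In the sham list 86.0% of regions (85.3 to 86.6%) overlapped a PHx region, where shuffled regions gave 12.2% on average, and 77.5% of PHx regions (76.7 to 78.3%) overlapped a sham region, against 11.9% by shuffling. PHx regions covered 87.3% of the sham length, and sham regions covered 53.9% of the PHx length. There were 2287 regions in PHx only, with a median width of 12101 bp, and 1627 in sham only, with a median width of 6018 bp. Absence from a merged list does not mean absence from both libraries of that group. Only 130 PHx-only and 275 sham-only regions lay in stretches where neither library of the other group had an unused peak number, and with a reciprocal overlap of 50% 5288 of 10170 PHx and 6720 of 11602 sham regions had no partner. Most regions were then not shared, and the order of the groups turned in both settings. Unused numbers were more common in the sham libraries, so the setting that uses them removes more PHx-only regions by its nature.

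Among 7090 protein-coding genes with a listed TSS, 4682 were marked in both groups, 1091 in PHx only, 694 in sham only and 623 in neither. Genes are counted here by the window at the TSS, so their regions can overlap a region of the other group elsewhere. The widest region at a promoter marked in PHx only spanned 199126 bp on chromosome 9 (107410029 to 107609154) and covered the TSSs of Tmem115 and Cyb561d2. It held a sham region of 96079 bp (107421184 to 107517262) that reached neither TSS window. Next came Denn2b (120825 bp), Dlc1 (101121 bp), Adap1 (99656 bp) and Ak1 (97661 bp), the cytosolic adenylate kinase. The PHx region at Ak1 also covered the promoter of Eng, which was marked in both groups, with a sham region of 13310 bp. Itga2b, the platelet integrin alpha IIb, and Fam171a2 shared a region of 87685 bp, followed by Mogat2 (84587 bp) and Myo15b (81441 bp). In sham only the widest were at Dnajb3 (61075 bp), Hs1bp3 (34441 bp), Pola2 (22777 bp), which encodes a subunit of DNA polymerase alpha, and Armc12 (22318 bp). Sbsn, Lamb2, Rgs12, Clstn3, Celf5 and Sgms2 followed with 22138 to 19437 bp. Where the one-group promoter had to lie in a stretch without unused numbers of the other group, 111 PHx-only and 101 sham-only genes were left. By the authors' own gene assignment the order turned, with 973 genes in PHx only and 1353 in sham only.

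The fixed endothelial markers with a listed TSS that had a promoter region had it in PHx only. Of the 8 fixed endothelial markers with a listed TSS, 6 were marked in PHx only, 0 in sham only and 0 in both. They were Lyve1 (region of 38368 bp), a hyaluronan receptor of sinusoidal and lymphatic endothelium, Erg (31257 bp), an endothelial ETS factor, Pecam1 (21591 bp), which encodes CD31, Bmp2 (16919 bp), Cdh5 (14699 bp), which encodes VE-cadherin, and Clec4g (10366 bp). Stab2 and Vwf were marked in neither group. Stab1, Kdr and Tek had no listed TSS, so their state is unknown in both groups. Only 0.01% of matched random lists had a net count as high, and it was the only 1 of the 22 fixed lists to pass the limit. The nearest sham region lay 198678 bp from the TSS of Erg and 135014 bp from that of Cdh5. At Lyve1 it ended 1298 bp from the TSS, so that promoter was narrowly outside. All 6 genes lay in stretches of the sham list with unused peak numbers of at least 1 sham library, and the list's net count was 0 once such genes were left out. Of all 1091 PHx-only protein-coding genes only 111 lay in stretches without one, so this is not particular to these markers. An unused number is placed in a stretch, which can be long, and not at the promoter.

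**Figure D2:**
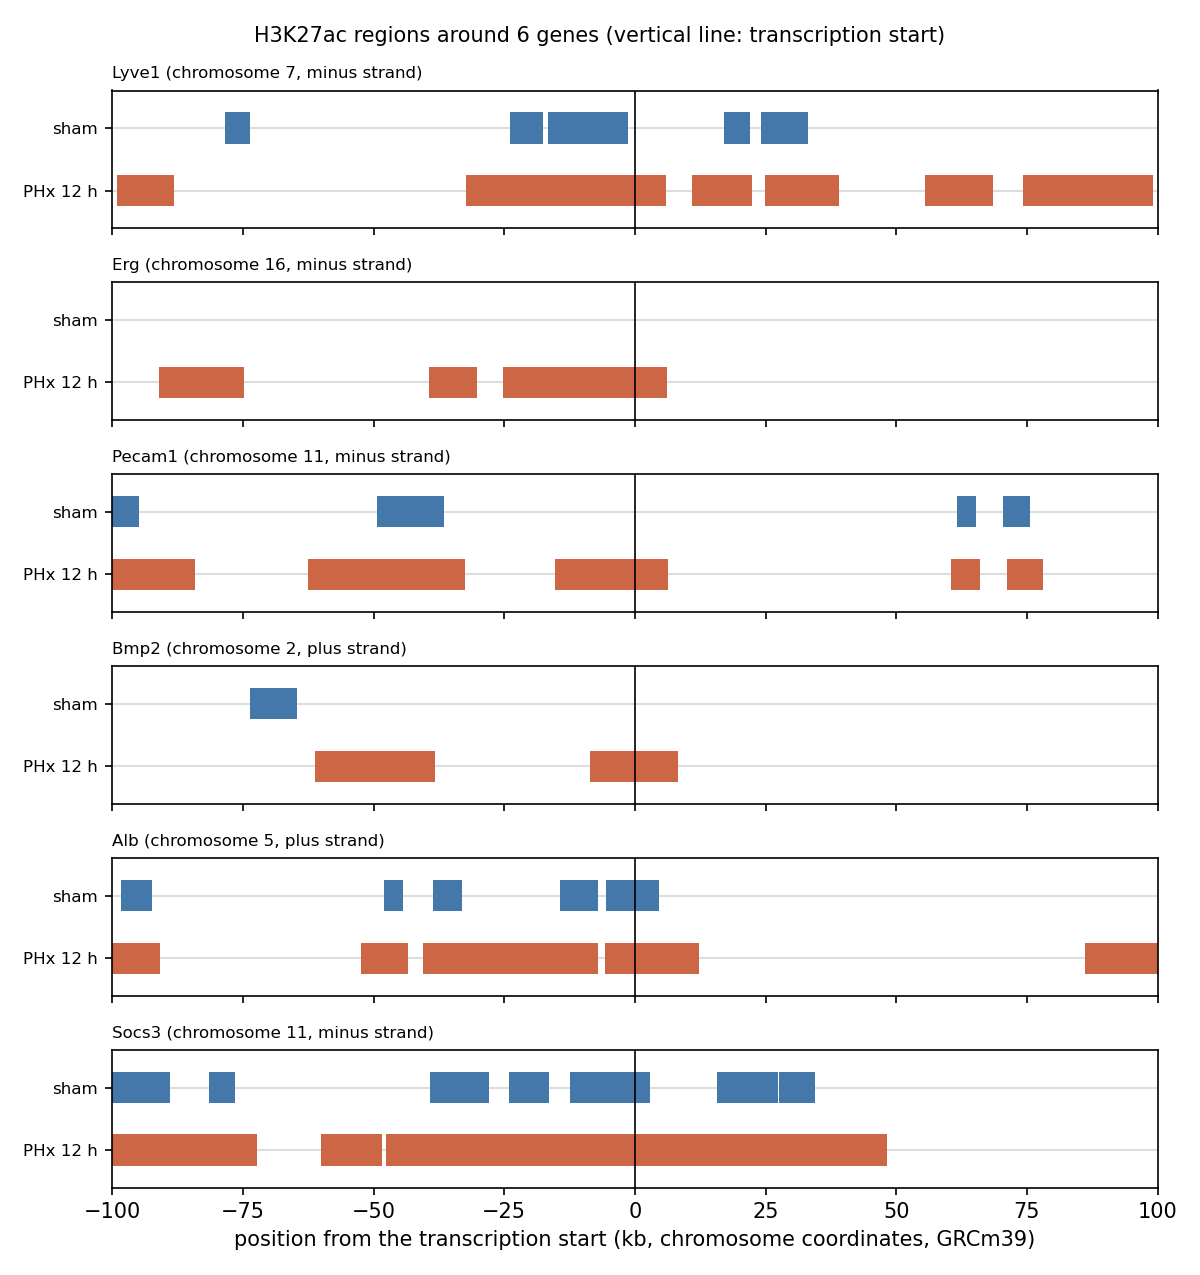
Regions within 100 kb of the TSS (vertical line) of the 4 endothelial markers marked in PHx only that had the widest promoter regions, of Alb and of Socs3, drawn to scale along the chromosome (x axis, kb), for sham (blue) and PHx 12 h (orange). Within this window Erg had 3 PHx regions and 0 sham regions, and at Socs3 a single PHx region of 95855 bp covered the place of several sham regions.

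Of the lists added for other liver cells, the endothelial and the stellate cell lists passed the limit of 2.5% on the PHx side and the Kupffer cell list did not. In the added endothelial list 8 of 27 genes were marked in PHx only (Ehd3, Elk3, Gata4, Plvap, Cd93, Cyyr1, Robo4 and Ramp2), 1 in sham only (Nos3, endothelial nitric oxide synthase) and 15 in both, and 1.97% of random lists were as high. In the added stellate cell and fibroblast list 6 of 11 were in PHx only (Col4a1, Bgn, Mylk, Tpm2, Cygb and Sparc) and 0 in sham only, with 0.12% of random lists as high. In the added Kupffer cell and macrophage list 4 of 12 were in PHx only (Cd14, Ly86, Pld4 and Mpeg1), 8 in both and 0 in sham only, and 3.82% of random lists were as high. The PHx-only genes of the added endothelial and stellate lists all lay in stretches with unused peak numbers of a sham library, as the fixed markers did, so none would stay without such stretches; Cd14 and Ly86 had no such number. Among the fixed markers, Csf1r of Kupffer cells and Colec11 of stellate cells were in PHx only, Cd68, C1qa and Ecm1 in both, and these lists had 3 and 2 members with a TSS. Sox9 of cholangiocytes was marked in both groups, and no marker of neutrophils and monocytes or of lymphocytes had a listed TSS. Of the genes of other tissues only Snap25 had one, and it was marked in neither.

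Genes of the early response to hepatectomy were already marked in sham, and several had much wider regions after PHx. Of the 12 immediate early and AP-1 genes with a TSS, 11 were marked in both groups, and Ier3 in PHx only (21387 bp). The promoter region of Btg2 measured 11527 bp in sham and 56919 bp after PHx, Atf3 7622 and 36270 bp, Fos 12569 and 45453 bp, and Nr4a1 32126 and 66336 bp. Egr1 had 19848 and 21657 bp. The median ratio of the list was 1.67, and 40.1% of random lists matched on sham width were as high. For the IL-6/STAT3 and acute phase genes, 11 of 12 were in both and Apcs, serum amyloid P, was in PHx only. The region of Socs3, the feedback inhibitor of STAT3 signalling, went from 15412 to 95855 bp, that of Itih4 from 11712 to 98169 bp and that of the interleukin-6 receptor gene Il6ra from 10656 to 33318 bp. Here the median ratio was 2.64, with 1.5% of random lists as high. It was 2.40, with 7.47% as high, when the fibrinogen genes Fga, Fgb and Fgg, which shared a PHx region of 58815 bp, were counted once. The sham regions at Fgg, Fga and Fgb (22305, 17144 and 14945 bp) were neighbours that together filled most of that PHx region. Their ratios thus largely reflect joined regions, also when counted once by their median ratio, and 2.64 was the ratio of Fgg itself. The PHx region of Socs3 likewise covered several sham regions. These list values therefore do not by themselves show more acetylated length.

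Growth factor genes and the few cell cycle genes with a TSS did not stand apart from random lists. Tgfa, a ligand of the EGF receptor, had the largest ratio among listed genes, 20.2, from 3250 bp in sham to 65560 bp after PHx. Igf1 went from 14075 to 75705 bp, Met, the receptor of hepatocyte growth factor, from 10505 to 31887 bp and Egfr from 28905 to 51626 bp. Tgfb1 had 8443 and 11577 bp and Tgfbr1 9809 and 12243 bp, and the median ratio of the list was 1.67, with 54.6% of random lists as high. Inhba (20054 bp) and Fst (12989 bp), which encode an activin subunit and its antagonist follistatin, were in PHx only, 9 of 11 were in both, and 30.6% of random lists were as high. Of 8 G1/S and replication genes, Cdk2 was in PHx only (14988 bp), E2f1 in sham only (6312 bp), Mcm10 in neither and 5 in both. Cdt1, a replication licensing factor, went from 6263 to 48849 bp and E2f2 from 8151 to 54447 bp, while Ccnd1, cyclin D1, had 36761 and 34313 bp. Of 4 G2/M genes, Aurkb was in PHx only (20117 bp) and Cdk1, Aurka and Birc5 in both. On net count, random lists were as high in 82.0% and 35.4% of draws for these lists. The median width ratio of the 5 G1/S genes in both groups was 2.20, with 18.6% of random lists as high.

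The promoters of hepatocyte identity genes were marked in both groups. All 13 hepatocyte transcription factors with a TSS were in both lists, among them Hnf4a (35346 and 85422 bp), Cebpa (44114 and 63908 bp) and Rxra (118578 and 117845 bp). Ppara, a regulator of fatty acid oxidation, had 25724 bp in sham and 130902 bp after PHx, and Nr1h4, the bile acid receptor FXR, 6726 and 38443 bp. A narrower region after PHx was found at Nr1h3, the oxysterol receptor LXR alpha, with 16937 and 6953 bp. Of 13 bile acid genes 12 were in both, including Slc27a5 (39768 and 50895 bp) and Abcc2 (30234 and 44841 bp). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had no promoter region in either group and a distal region in PHx only. Of the added hepatocyte genes 21 of 23 were in both, among them Apoa1 and Itih3, and Hao1 was in PHx only, with 51.4% of random lists as high.

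Metabolic, clock and stress genes were mostly shared as well. Of 12 periportal genes 10 were in both, including Asl (30113 and 51764 bp), and Cps1, the first enzyme of the urea cycle (29267 bp), and Hsd17b13 (21120 bp) were in PHx only. Of 7 pericentral genes, Axin2 was in PHx only (13131 bp) and Znrf3 in sham only (13449 bp), both Wnt pathway regulators, and Rnf43 went from 9791 to 78254 bp. Among 13 lipogenesis and cholesterol synthesis genes, Sqle was in PHx only (12666 bp), Scd1, the stearoyl-CoA desaturase, in sham only (9357 bp) and 10 in both, with Elovl6 going from 14959 to 74007 bp. Pdk4 (5207 bp) and Cyp4a14 (10869 bp) were the 2 of 10 fatty acid oxidation genes in PHx only. The other 8 were in both, with a median width ratio of 1.12 that 3.29% of random lists reached or fell below; Cpt1a went from 8511 to 46104 bp. Per3 was the single clock gene in sham only (8403 bp), 11 of 12 being in both, and Ccng1 the single stress gene in sham only (4893 bp), 10 of 11 being in both. Among the 6 ribosome biogenesis genes Pes1 was in PHx only, Bop1 in sham only, Nolc1 in neither and 3 in both. Of 7 housekeeping genes 6 were in both and Ywhaz in neither. None of these lists, nor the hepatocyte lists, passed the limit on net count in either direction. By the authors' own gene assignment the clock genes did, with a net count of -5 that 1.16% of random lists reached or fell below. That assignment counts a region only for the 1 gene it names. As 11 of the 12 clock genes had a region at the TSS in both groups, the -5 does not show clock promoters without a region after PHx.

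**Figure D3:**
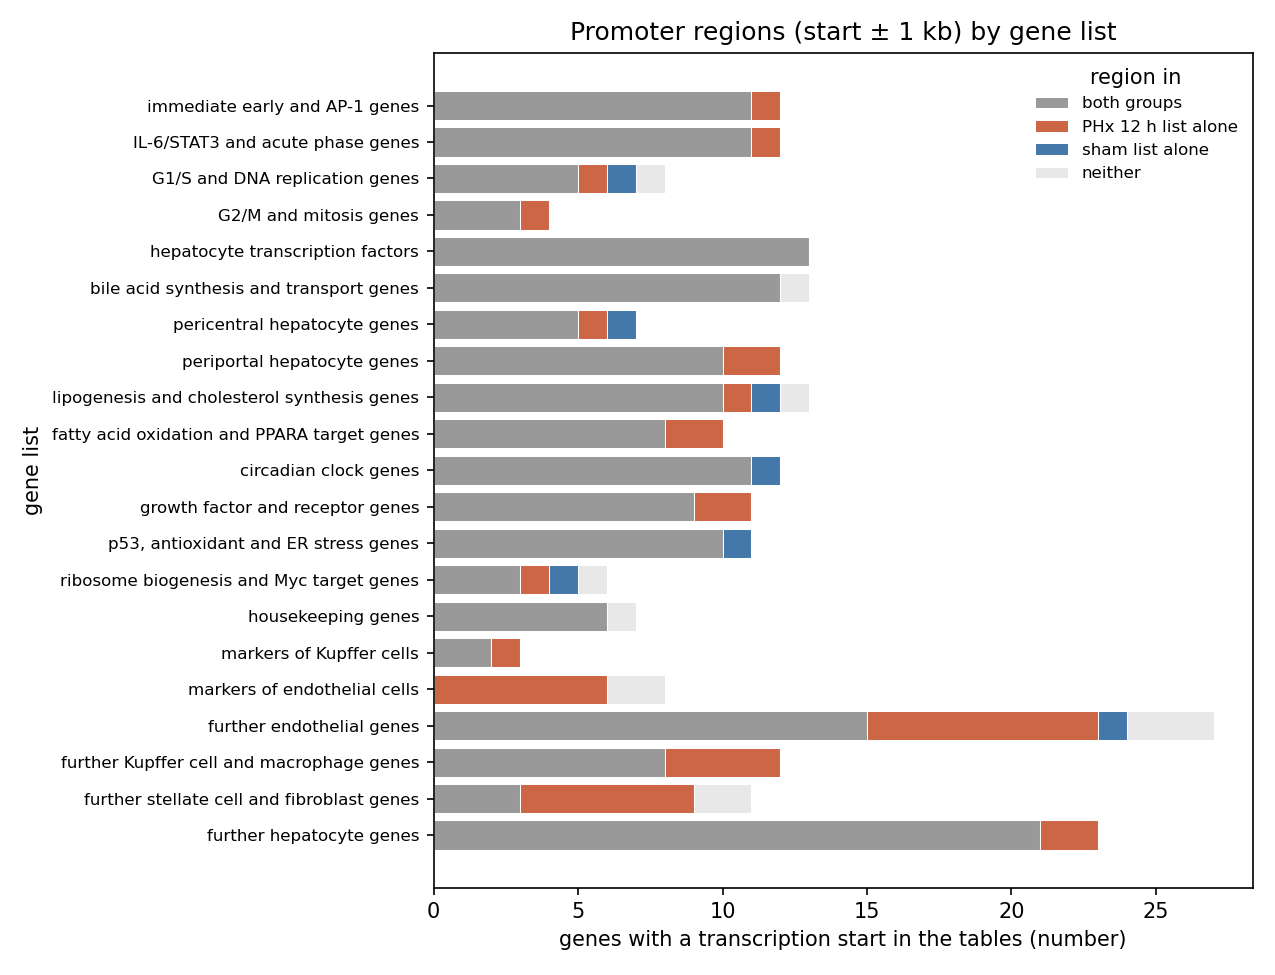
Number of genes (x axis) with a listed TSS in each list with at least 3 such genes (y axis), by whether a region overlapped TSS ± 1 kb in both groups (grey), in PHx 12 h only (orange), in sham only (blue) or in neither (pale). The 6 PHx-only genes of the first endothelial list make up all of its marked members with a listed TSS. All 13 hepatocyte transcription factors with a listed TSS are marked in both groups.

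Distal regions, over 3 kb from the nearest TSS, were fewer after PHx, and how many were in one list only depended on the definition of overlap. The lower number is the other side of the larger promoter share, and greater width alone lowers it. There were 2505 distal regions after PHx, of which 942 (37.6%) had no overlap in sham, and 3738 in sham, of which 695 (18.6%) had none after PHx. The widest in PHx only were nearest to Gm22595 (chromosome 9, 102903321 to 102952415), Map4k4 (intron, 41050 bp), Gm14010 (41028 bp), Gm28821 (38174 bp) and Ctdspl (intron, 35598 bp). In sham only they were nearest to Khdc1a (22190 bp), Cnmd (18289 bp), Gm32756 (17834 bp), Zp2 (15862 bp) and Mras (14561 bp). For the fixed endothelial markers 3 of 8 distal PHx regions were in PHx only, at Erg and Stab2, and 0 of 5 sham regions were in sham only. For the added stellate cell and fibroblast genes all 3 sham distal regions were in sham only, at Col6a2, Mylk and Tpm2, and both distal PHx regions in PHx only, at Gata6 and Nid1. Those counts have no random lists beside them. The order of the groups turned with a reciprocal overlap of 50%, which gave 1538 distal regions in PHx only and 2659 in sham only, and without unused peak numbers, which left 58 and 140. The latter setting removes more PHx-only regions, since unused numbers were more common in the sham libraries.

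The widest 1% of regions were at least 40545 bp wide in sham and 80245 bp in PHx, with 69 and 122 protein-coding genes at their TSSs, of which 20 were shared. The shared genes included Apoa1, the main HDL apolipoprotein, and Rxra. Socs3, Itih4, Hnf4a and Ppara were among these genes after PHx and not in sham. The limits of width differ, so a gene can leave the set without narrowing, as did Cebpa (44114 and 63908 bp) and Rora (59112 and 61203 bp). The widest region of all, on chromosome 8 (127380788 to 127638556), measured 257769 bp after PHx and was assigned to A630001O12Rik. Next after PHx were those at Cyb561d2, 2210408F21Rik (161938 bp), Cmip (145919 bp) and Gm34065 (138743 bp). In sham the widest were at Mir3075 (123534 bp), 4930544F09Rik (120721 bp), where Mtss1 starts, Rxra (118578 bp), Gm39664 (101781 bp) and Gm34106 (96079 bp).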

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

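The settings by width, by unused peak numbers, by regions apart from the other group and by placing genes among neighbours were chosen after seeing the data. The ratio of covered length (1.62) and the ratio of median width (1.78) stayed above 1 in all settings run, the latter between 1.49 and 1.87. The settings that choose regions by width follow from the width distribution itself and are no separate check of these ratios. The promoter share was 80.5% of covered length after PHx and 72.2% in sham, and 79.8% and 71.3% among the widest 50% of regions. Requiring a reciprocal overlap of 50% raised PHx-only regions from 2287 to 5288 and sham-only regions from 1627 to 6720, and distal ones from 942 and 695 to 1538 and 2659, which turns the order of the groups; unequal widths alone can fail this criterion. In the widest 50% there were 548 and 462 distal regions of one group, from fewer regions. Leaving out places with an unused number of the other group left 130 PHx-only and 275 sham-only regions, 58 and 140 of them distal, which again turns the order, and 111 PHx-only and 101 sham-only genes. Of stretches of like length without a one-group region, 40.6% in the sham list and 61.9% in the PHx list had no unused number. More PHx-only than sham-only regions therefore drop out by the nature of this setting. In that setting 0 gene lists were apart and the endothelial net count was 0 instead of 6; it removes most one-group genes by construction. In the other settings the endothelial net count was 5 or 6 and stayed past the limit, also with regions that touch no sham region (5, reached by 0.01% of random lists). With equal numbers of regions by width, 1648 genes were in PHx only and 456 in sham only, since the sham list lost its narrowest regions. With the authors' gene assignment 973 genes were in PHx only and 1353 in sham only, against 1091 and 694 as reported, so the order turned, and 2 lists were apart; the other was the clock genes, with a net count of -5 that 1.16% of random lists reached. That assignment counts a region only for the 1 gene it names, which lowers counts where wide regions cover several TSSs. Of the 12 clock genes 11 had a region at the TSS in both groups, so the -5 reflects which gene a region was named for. Whether this accounts for the whole turn was not tested. Genes shared by the broadest domains rose from 20 to 144 in the widest 5%, which holds more regions, and to 33 with regions within 3 kb joined. In all, 45 of the values under alternatives stayed within 1.5 times the reported count or ratio, within the 95% interval of a share, or on the same side of the list limit, 23 moved and 1 lost its side of the limit. Placing unlisted genes by gene order settled few of them. Not run were thresholds by signal, which the tables lack, motif shares, which need a genome, and the test per gene with its left-out replicates, replicate block and DESeq2, which need values per library. No paired analysis was possible because the tables hold 1 merged list per group, although the labels number the libraries alike. Unknown depth limits every statement on absence.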

Other observations

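The tests of joined peaks, of extra wide regions, of peaks in 1 library, of more sensitive calling and of a lower share of hepatocytes, the ratio in the widest pairs and the comparison of pathways were chosen after results were seen. Among 268 KEGG pathways with at least 15 genes in the authors' annotation, 8 had a PHx excess that at most 1% of matched random lists reached. The nominal number, 1% of 268, is 2.68. Cell adhesion molecules led, with 17 genes marked in PHx only, among them Vcam1, Icam2, Selplg, Itgav and the endothelial Cdh5 and Pecam1, 2 in sham only (Glg1 and H2-M3) and 0.04% of random lists as high. Cytokine-cytokine receptor interaction had 23 in PHx only and 5 in sham only (0.11%), including Osmr and Lif of the interleukin-6 family, Il1rn, Il10ra, Csf1r and Bmp2. Hematopoietic cell lineage (9 and 1 genes, 0.12%), leukocyte transendothelial migration (14 and 0, 0.41%), regulation of actin cytoskeleton (20 and 2, 0.47%), focal adhesion (23 and 5, 0.64%), ECM-receptor interaction (11 and 3, 0.70%) and axon guidance (16 and 2, 0.96%) followed. Their gene sets overlap, and the genes named here were picked after their values were seen.

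On the sham side 4 pathways were as low as at most 1% of random lists, close to the nominal 2.68. Net counts are whole numbers with ties, and pathways share genes, so the number by chance can differ from 2.68. The counts of pathways on both sides are therefore descriptive. The Fanconi anemia pathway of DNA crosslink repair had 8 genes in sham only, Atrip, Blm, Brip1, Ercc4, Fancc, Fance, Telo2 and Top3b, and 2 in PHx only, Fancg and Fancm (0.67%). The pathway named amyotrophic lateral sclerosis had 20 genes in sham only and 13 in PHx only (0.58%), the former including the respiratory chain genes Ndufb8, Ndufv2 and Cox5b and the proteasome genes Psma1, Psmb2 and Psmd4. The latter included the respiratory chain gene Ndufb4 and the proteasome genes Psmb3, Psmb4, Psmc4 and Psmd7. The proteasome pathway itself had 4 genes in PHx only and 4 in sham only. Cortisol synthesis (6 and 1 genes, 0.73%) and cocaine addiction (4 and 0 genes) shared Atf2 and Prkacb.

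The X chromosome carried few regions in either list: 30 of 11602 in sham (0.259%, 95% interval 0.175 to 0.369%) and 50 of 10170 after PHx (0.492%, 0.365 to 0.648%), while 4.41% of RefSeq protein-coding genes are on X. Peak numbers of single libraries were equally rare there, 0.264% and 0.366% in sham and 0.513% and 0.608% after PHx. Peak numbers reached 17405 and 17476 in the sham libraries and 12096 and 14957 in the PHx libraries, of which 73.3%, 71.4%, 87.6% and 78.8% were inside listed regions.

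Endothelial promoters in the PHx list may reflect a lower share of hepatocytes among the nuclei, as a hypothesis. It predicts a like gain at other cell types. Of 82 Kupffer and stellate genes 28 had a TSS, and 42.9% of these (12 of 28, 24.5 to 62.8%) were in PHx only. The share was 40% of endothelial genes (14 of 35, 23.9 to 57.9%), 15 of those 35 being marked in both groups. Among all 7090 protein-coding genes 1091 were in PHx only. A gene has a listed TSS only where a region of either group names it, so a PHx-only region can itself bring a gene into these counts. Of all members, with or without a TSS, 12 of 82 Kupffer and stellate and 14 of 51 endothelial genes were in PHx only. How alike the gains are thus depends on this filter. No marker of neutrophils and monocytes or of lymphocytes had a TSS, nor did most cholangiocyte markers, so the prediction could not be checked there. Separately, the shares were 53.8% of stellate genes (7 of 13, 25.1 to 80.8%) and 33.3% of Kupffer genes (5 of 15, 11.8 to 61.6%). These intervals overlap widely, and the difference was not tested. On net count, 0.02% of random lists were as high for the stellate and 1.85% for the Kupffer genes. The latter became 4.41% with regions apart from the sham list. More sensitive calling after PHx cannot be told apart: 0.01% of random lists had a net count as high as 6, the value by which the list stood out, but they were not matched on closeness to the calling threshold, and without stretches that held unused sham peak numbers, where all 6 genes lay, the net count was 0 and 93.3% were as high. That setting kept only 111 of all 1091 PHx-only protein-coding genes, so the loss of these 6 says little about this explanation. The choice of markers stays open, since the second endothelial list was reached by 1.97% of random lists, between the bounds of 1% and 5% set beforehand. A response to hepatectomy within these cells was not tested and stays open.

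Wider regions in PHx were not accounted for by the joining of several listed peaks alone, as regions of 1 peak per library had a ratio of median widths of 1.73. Among 5004 pairs of such regions, matched 1 to 1, the median ratio was 1.51. Extra wide regions in PHx only are argued against as well, since regions paired 1 to 1 had a median ratio of 1.49. Neighbouring signal joined by the caller into 1 peak cannot be seen in these counts and stays open. A single PHx region overlapped several sham regions in 1614 cases, and the reverse occurred in 85. A general difference in calling or background may contribute, since the median ratio at the 6 housekeeping promoters marked in both groups was 2.23. It should also reach narrow and wide regions alike. The ratio was 1.97 in the pairs narrowest in sham and 1.17 in the widest, although sorting by sham width itself pulls these values apart. In bp the gain was alike, with medians of 4930 bp in sham and 9448 bp after PHx in the narrowest pairs. In the widest pairs the medians were 16530 and 21357 bp. The falling ratio therefore does not argue against a general difference. Each region is the union of the peaks of both libraries, so the widths cannot be traced to 1 library or to both. In the PHx group library 2 alone was split into several peaks in 1173 regions and library 1 alone in 246. Whether broad peaks of a single PHx library widened the list was not tested. With depth and thresholds unknown, a general difference in calling and a widening of acetylation by hepatectomy both stay open.

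Regions listed in one group only may be peaks of 1 library in the other group. Stretches of the PHx list that held a sham-only region had 0.734 more unused peak numbers (bootstrap 95% range 0.681 to 0.790) than stretches of like length, and stretches of the sham list that held a PHx-only region had 1.001 more (0.923 to 1.08). Of the latter stretches 9.21% had no unused number, against 40.6% of stretches of like length. By library the excess was 0.173 in library 1 and 0.561 in library 2 of the PHx group, and 0.441 and 0.561 in those of sham. How many of the regions listed in one group only differ in both libraries, and whether hepatectomy is the reason, was not tested and stays open.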
